A study of Mus musculus with 12 samples.

How the data were processed

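RNA samples from cultured adult mouse cardiac myocytes, 6 with 200 nmol/L recombinant CTGF for 48 h and 6 without it, were hybridised to single-colour Illumina bead arrays with a biotin label, per the labels' protocols. The authors deposited a table of average bead intensity per probe and array on a linear scale, not normalized, per the file headers. The same deposited table gives a detection p-value for each probe and array, per the file headers. A further deposited table holds intensity values that are the same in distribution on every array. Its sorted columns lay within 0.65% of the mean of the sorted raw columns, leaving out the top 10 probes, and each column's rank correlation with its own raw column was at least 0.999996. These values therefore match quantile normalization of the raw intensities without background subtraction. Scanner software, any earlier background step and slide positions are not given in the sources used here. The sample descriptions number all CTGF samples before all controls. A slide or batch that goes with the treatment therefore cannot be told apart from it in any comparison below. Medians of the authors' normalized columns lay between 73.14 and 73.23.

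Groups and replicate numbers came from the sample titles. Of 45281 probes, 34885 had 1 gene symbol in the platform annotation, 18 had several and 10378 were not listed with a gene. Genes were named through Entrez identifiers (34807 probes) or accessions (11 probes) of the GRCm38.p6 gene table, which updated 10 symbols, and 67 probes kept the symbol of the annotation. No coordinates are given, since the files name no genome build.

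Raw intensities were normalized with neqc in limma 3.58.1 (R 4.3.3), which estimates the background from the detection p-values, adds an offset of 16, quantile normalizes and takes log2. The offset shrinks fold changes of dim genes. A probe was kept if detected at p under 0.05 on at least 6 arrays, which left 15038 probes, 13029 of them with 1 symbol. Each gene was represented by its brightest probe, giving 8905 genes, of which 3012 had over 1 detected probe and 54 had probes called in both directions. CTGF and control arrays were compared with lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over these genes and a threshold of 0.05. Errors of log2 fold changes are limma standard errors. Where all probes of a gene were undetected in a group, a bound is given.

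Of 33 gene lists, 27 had at least 5 measured genes and were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 27. An estimated correlation and fry were alternatives. Fry tests whether the genes of a list move on balance in 1 direction, without comparing them with other genes, and it called 21 lists, 18 of them lower. Its mixed test, for change in either direction, called 27. The groups, tests, gene lists, rule for named genes and alternatives, except those the closing section names as added later, were fixed before the data were examined. The rule took Ccn2, the 15 largest rises and 15 largest falls among called genes with a proper gene name, and from each list up to 4 called members with the largest absolute change, or the 2 brightest where fewer than 2 were called. The text names fewer than the 128 genes of the rule.

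The other settings were no background correction, normexp on each array's own signal, 3 other scalings between arrays, the authors' normalized values, other detection filters and probe summaries, array weights, a trended robust variance, stricter thresholds, a replicate block and leaving out each array. The closing section gives their effect.

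The fit was tested on simulated intensities for the CTGF and control comparison, with the background of each array as limma fits it and 200 genes changed by known amounts. A first simulation with an assumed background recovered too few genes for a limit set in advance, and was replaced after that was seen. The limit was then applied to bright genes alone. With each probe's own spread, over 9250 genes, 66.0% of genes raised by 1 on the log2 scale, 80.9% of those lowered by 1, 42.9% of those raised by 0.5 and 46.9% of those lowered by 0.5 were recovered. Among genes with a mean log2 of 8 or more, 92.3% raised by 1 and 100% lowered by 1 were recovered. Of the calls 5.74% were unchanged genes. With a lower spread in dim genes, over 9256 genes, recovery was 79.6% for a rise of 1 and 79.2% for a fall of 1. The first spread was the closer of these to the real one, at 0.21 against 0.22 for probes with a mean log2 of 6 to 7, where the other gave 0.16. Without changed genes neither simulation called a gene, and both called the 3 shifted lists and no other. Noise was drawn for each probe separately, so simulated genes of a list were not correlated. The real endothelial and interferon lists had estimated correlations of 0.34 and 0.20. The simulation therefore does not test false list calls among correlated genes. It changed 200 genes, as many up as down, while the real comparison called 4080 of 8905. With so few changed genes the adjusted threshold is stricter, so the recovery rates do not carry over to the real comparison. Nor does the simulation test how the scaling between arrays moves the balance of rises and falls. Figures were drawn with matplotlib 3.10.9.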

Results

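Adult cardiac myocytes from C57BL/6 mouse hearts were cultured with recombinant connective tissue growth factor (CTGF, also called CCN2) or without it, and their RNA was measured on Illumina bead arrays. CTGF is a secreted matricellular protein of the CCN family. The added protein was at 200 nmol/L and the culture lasted 48 h. Each group had 6 arrays, 12 in all. The series design gives 6 cultures with and 6 without CTGF. The labels do not say whether these came from separate hearts or preparations. The p-values therefore measure the spread between these samples, which may be partly technical. The number of arrays limits the precision, and the median standard error of a log2 fold change was 0.11. Per array, 14747 to 16390 of 45281 probes were detected, with means of 15705 ± 503 (SD, n = 6) with CTGF and 15266 ± 407 (SD, n = 6) in controls (two-sided exact permutation p = 0.132). The raw median intensity was 73.1 ± 2.87 (SD, n = 6) with CTGF and 73.2 ± 0.897 (SD, n = 6) in controls. The raw 75th percentile was 103 ± 7.27 with CTGF and 95.6 ± 2.87 in controls (two-sided exact permutation p = 0.0628).

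The comparison asks which transcripts differ between myocyte cultures with and without CTGF. With CTGF, interferon-response and antigen presentation genes, endothelial marker genes and many immediate early genes were lower. Single genes for secreted and signalling proteins, among them Ccn4, Lcn2, Cxcl1 and Il11, were higher. Of 8905 genes tested with limma, 2187 were higher and 1893 lower at a Benjamini-Hochberg adjusted p under 0.05. At least 2-fold changes were fewer and mostly falls, with 133 genes higher and 345 lower. The 6 CTGF arrays and the 6 control arrays did not overlap for 25.1% of the genes, where chance gives 0.216%. The balance of rises and falls depended on the scaling between arrays. Of the called genes 53.6% were higher under quantile normalization, 86.3% without normalization between arrays, 85.0% under median scaling and 46.4% under cyclic loess. The median log2 fold change of all genes was 0.03 under quantile normalization, 0.35 without normalization between arrays and 0.32 under median scaling. Fold changes below are therefore relative to the other genes on the array. Sizes depended on the background too, with 35 of 126 called named genes over 1.5 times smaller on the log2 scale without background correction.

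The gene of the added protein, Ccn2, was lower in the treated cells, with log2 intensities of 12.61 ± 0.21 (SD, n = 6) against 13.22 ± 0.08 in controls. Its log2 fold change was -0.62 ± 0.10 (SE, limma adjusted p = 0.000142), and a second detected probe gave -0.71. All 4 measured members of the CCN family were called. Ccn4, a WNT-inducible member also known as Wisp1, had the largest rise of all named genes, from 6.70 ± 0.29 to 9.78 ± 0.18 on the log2 scale, a change of 3.08 ± 0.13 (SE). Ccn1 (Cyr61) fell by 1.18 ± 0.11. Ccn5 rose by 0.44 ± 0.14 from a level detected on 2 of 6 control arrays, and its call was lost without CTGF replicate 1 and control replicate 6, where its log2 fold change was 0.39.

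**Figure D1:**
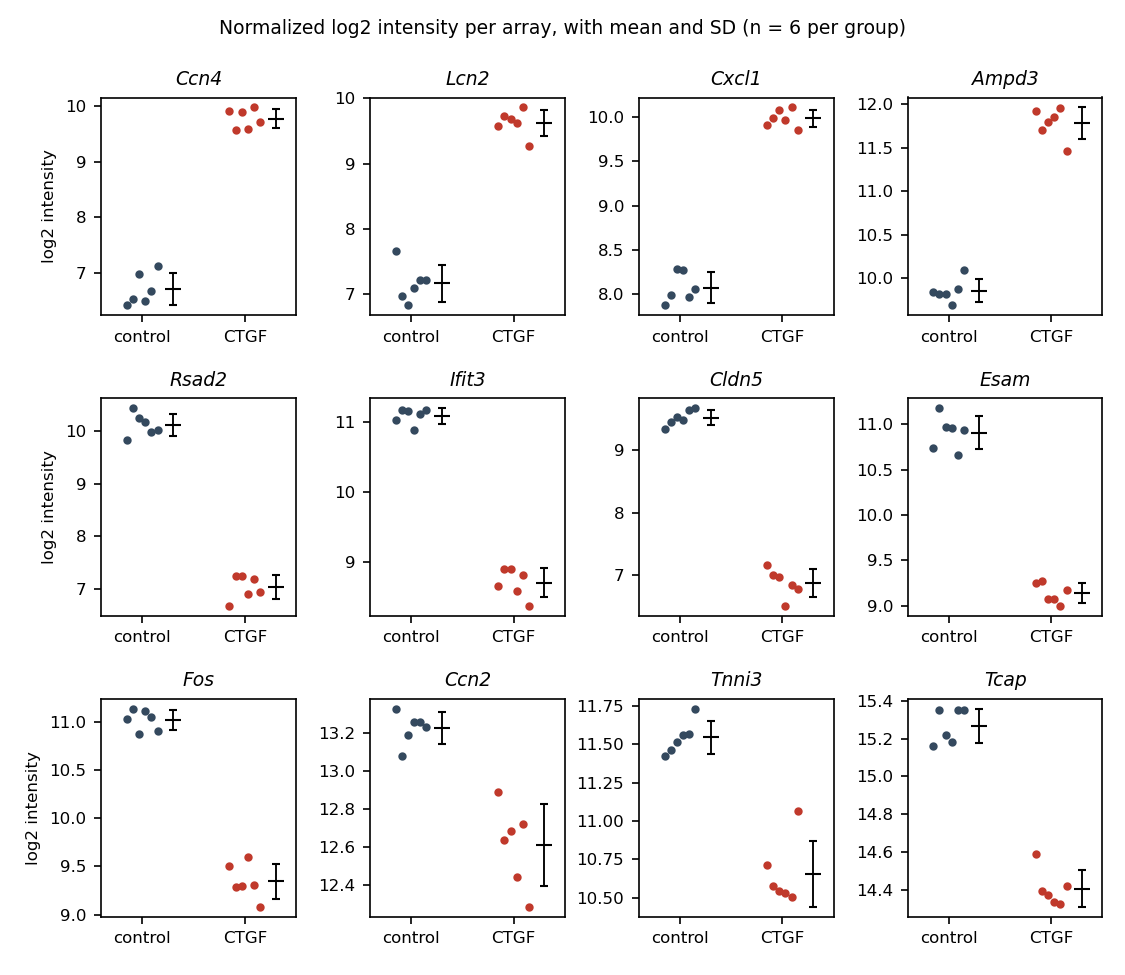
Normalized log2 intensity (vertical axes, which do not start at 0) of 12 genes on each of the 6 control and 6 CTGF arrays, with the mean and SD beside the points. In each panel the groups do not overlap, with Ccn4 rising by 3.08 and Rsad2 changing by -3.07 on the log2 scale.

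The 15 largest rises among named genes lay between 1.76 and 3.08 on the log2 scale. After Ccn4 came Lcn2, which encodes the iron-carrier-binding lipocalin 2, at 2.45 ± 0.13 (SE). Mylk2, the skeletal muscle myosin light chain kinase, rose by 2.42 ± 0.12. Dyrk3, a protein kinase, rose by 2.31 ± 0.13, and Slc40a1, the iron exporter ferroportin, by 2.21 ± 0.10. Ampd3, an AMP deaminase, rose by 1.93 ± 0.10. The neutrophil chemokine gene Cxcl1 rose by 1.90 ± 0.09, the cytokine gene Il11 by 1.91 ± 0.21, and Cish, an inhibitor of cytokine signalling, by 1.80 ± 0.09. The gelatinase gene Mmp9 rose by 1.80 ± 0.13, and was detected on 4 of 6 control arrays. The integrin subunit gene Itgb6 rose by 1.76 ± 0.12, with 0.92 and 1.67 at its other probes. Bcr, Phox2a and Fem1b were the remaining rises, at 1.84, 1.84 and 1.83. Serinc2 was not above background on any control array and was at least 3.61-fold higher with CTGF. Bounds of this kind set the bright group's mean against the lowest signal of detected probes on the dim arrays, or the gene's own signal there if higher.

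The 15 largest falls lay between -3.37 and -2.34. The largest were in Ly6c1, a surface antigen of endothelial and myeloid cells (-3.37 ± 0.16, SE), and in Rsad2, an antiviral interferon-induced gene (-3.07 ± 0.12). The water channel gene Aqp1 changed by -2.98 ± 0.08, and its 2 other detected probes were also lower. The cytokine gene Tslp changed by -2.94 ± 0.16 and the apelin receptor gene Aplnr by -2.90 ± 0.13. Cldn5, an endothelial tight junction gene, changed by -2.63 ± 0.11. Gpihbp1, the endothelial anchor of lipoprotein lipase, changed by -2.34 ± 0.11, and the growth factor receptor gene Pdgfra by -2.35 ± 0.11. Aplnr was detected on 1 and Gpihbp1 on 2 of 6 CTGF arrays, so their sizes are set against signals mostly not above background. Gpnmb, Ifi27l2a, Gvin1, Lyz1, Ifit3, Ifit2 and Ly6e were the other falls. Lyz1 has a close paralog, Lyz2, which a probe may also bind.

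All 22 measured genes of the interferon response and antigen presentation list fell, with a median log2 fold change of -1.87. The same 22 were called when adjusted over the list alone. The list was called by camera (adjusted p = 7.59e-20), and its adjusted p was 0.0258 with an estimated correlation, the only list to keep its call there. Ifit3 and Ifit2, interferon-induced RNA-binding proteins, changed by -2.39 ± 0.10 and -2.38 ± 0.14 (SE), with -1.51 at a second Ifit3 probe. Irf7, a transcription factor of the interferon response, changed by -2.27 ± 0.10. Probes of the histocompatibility, Ifit and Gbp families can bind close paralogs. On the same arrays all 12 measured endothelial markers were lower.

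The endothelial markers had a median log2 fold change of -1.66, and all 12 fell, also when adjusted over the list alone (camera adjusted p = 6.41e-12). The adjusted p was 0.0753 with an estimated correlation. Besides Ly6c1 and Cldn5, Egfl7 changed by -1.80 ± 0.09 (SE) and Esam, a cell adhesion molecule, by -1.77 ± 0.09. Of 9 smooth muscle and pericyte markers 7 fell and 2 rose, with a median of -0.71 (camera adjusted p = 0.0361), and the counts adjusted over the list alone were the same. The adjusted p was 0.163 with an estimated correlation, and 0.32 over genes detected on all 12 arrays, where the median was -0.49. The median was -0.40 without background correction and -0.39 on the authors' normalized values. Mcam changed by -1.72 ± 0.10, the smooth muscle myosin gene Myh11 by -1.31 ± 0.18 and Notch3, detected on 3 of 6 CTGF arrays, by -1.26 ± 0.15, while Cspg4 rose by 0.84 ± 0.13. The other rise was Des (0.35 ± 0.08), which is counted on the sarcomere list too.

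**Figure D2:**
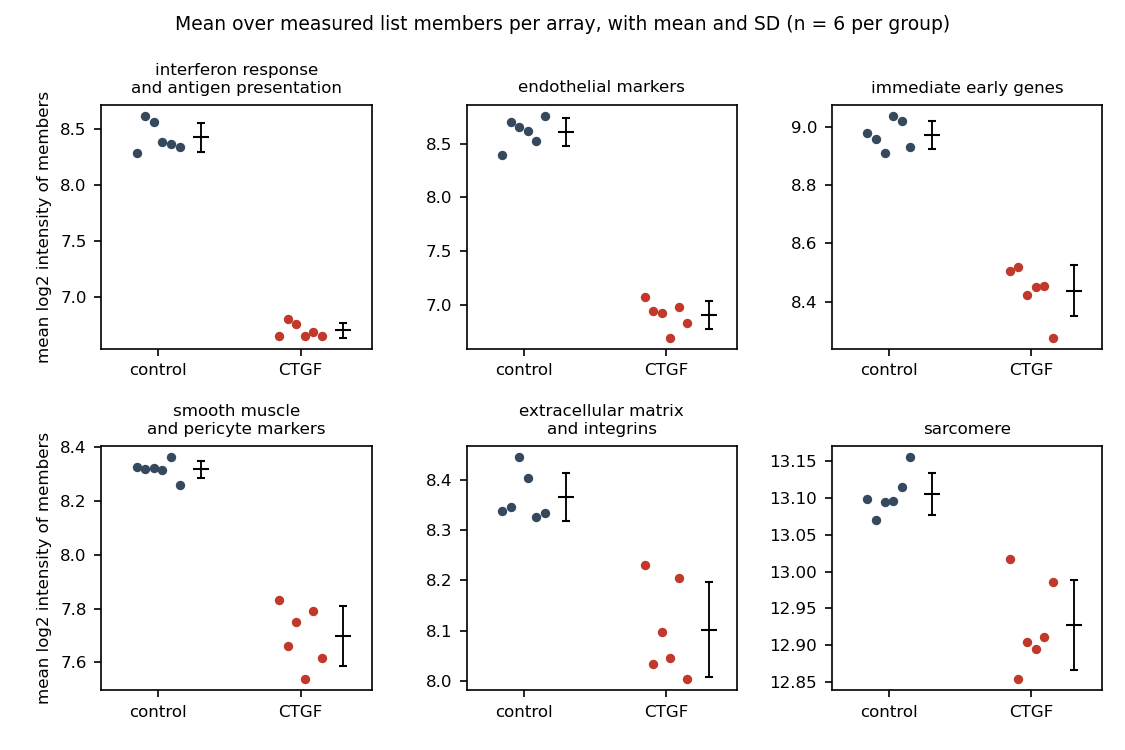
Mean log2 intensity over the measured members of 6 gene lists (vertical axes, which do not start at 0) on each of the 6 control and 6 CTGF arrays, with the mean and SD beside the points. The CTGF arrays lie below every control array in each panel, and the interferon list has the largest gap, with a median log2 fold change of -1.87 over its 22 genes.

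Of 9 fibroblast markers 4 fell and 1 rose (camera adjusted p = 0.308), and adjusted over the list alone 4 fell and 2 rose. Pdgfra changed by -2.35, Tcf21, a transcription factor of cardiac fibroblasts, by -1.43 ± 0.12 (SE) and Pi16 by -1.20 ± 0.15, while Meox1, a homeobox gene, rose by 1.15 ± 0.08. Tcf21 was detected on 2 of 6 CTGF arrays. Of 7 macrophage and myeloid markers 4 fell and none rose (camera adjusted p = 0.115), with Lyz1 at -2.41 ± 0.14 and Lyz2, detected on 2 of 6 CTGF arrays, at -1.07 ± 0.12. Camera called this list lower without normalization between arrays (adjusted p = 0.00381) and under median scaling (adjusted p = 0.00351). Of 7 atrial myocyte markers 4 fell (camera adjusted p = 0.115), among them Kcna5, which was not above background with CTGF and was at least 1.27-fold lower. The atrial list was called by camera with no detection filter (adjusted p = 0.0164). Without normalization between arrays the other 3 lost their call, Myl7 (adjusted p = 0.381), Myl4 (0.455) and Stard10, which turned to 0.13, and under median scaling the same 3 did. For both lists the counts adjusted over the list alone were the same. Krt8 was the 1 mesothelial marker measured and did not pass the test, at -0.18 ± 0.20. No lymphocyte, erythroid or Schwann cell marker on the lists was detected on at least 6 arrays.

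Of 18 immediate early genes, which respond within minutes to many stimuli, 12 fell and 3 rose, with a median of -0.59 (camera adjusted p = 0.000518). The adjusted p was 0.163 with an estimated correlation. The median was -0.30 without normalization between arrays and -0.33 under median scaling. The counts were the same adjusted over the list alone. The AP-1 subunit genes Fos, Jund and Jun changed by -1.67 ± 0.09, -1.51 ± 0.20 and -1.44 ± 0.09 (SE), and Klf4 by -1.24 ± 0.10, with -0.88 and -0.61 at its other probes. On the same arrays all 12 measured endothelial markers were lower. Glucocorticoid-responsive genes went both ways, 3 higher and 4 lower of 14 (camera adjusted p = 0.795). Among them Sgk1 changed by -1.41 ± 0.11 and Dusp1, a MAP kinase phosphatase, by -1.13 ± 0.09.

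Of 26 extracellular matrix and integrin genes 13 fell and 7 rose (14 and 7 adjusted over the list alone), with a median of -0.29 (camera adjusted p = 0.0411). The adjusted p was 0.428 with an estimated correlation. The median turned to 0.13 without normalization between arrays and to 0.10 under median scaling, below the median of all genes in both. The call was lost without CTGF replicate 2 and without control replicate 2, 3 or 5, with adjusted p up to 0.0754, and under cyclic loess (adjusted p = 0.0775). The collagen VI gene Col6a1 changed by -2.10 ± 0.10 (SE), the metalloproteinase genes Mmp2 and Mmp14 by -1.81 ± 0.10 and -1.42 ± 0.15, and Mmp3 rose by 1.64 ± 0.32, with 0.85 and 1.82 at its other probes. On the same arrays the endothelial markers (12 of 12 lower, median -1.66) and the fibroblast markers Pdgfra (-2.35) and Tcf21 (-1.43) were lower. In the whole fibroblast list of 9, 4 fell and 1 rose, Meox1 (1.15), and the list was not called (camera adjusted p = 0.308). In the TGF-beta response and fibrosis list 3 genes rose and 6 fell of 15 (camera adjusted p = 0.356). The BMP and TGF-beta targets Id2 and Id1 changed by -1.53 ± 0.14 and -1.43 ± 0.14, and the receptor gene Tgfbr2 by -1.17 ± 0.13. Lox, which cross-links collagen, was not above background in controls and was at least 2.68-fold higher with CTGF.

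The inflammation and chemokine list was split, with 10 genes higher and 6 lower of 24, the same adjusted over the list alone (camera adjusted p = 0.356). Lcn2 and Cxcl1 rose, while the chemokine gene Cxcl12 and the alarmin gene Il33 fell, Il33 by 1.52 ± 0.12 (SE) with detection on 4 of 6 CTGF arrays. Other Cxcl12 probes gave -1.58 and -0.74. In the complement and acute phase list, with 2 genes measured, Serping1 changed by -1.65 ± 0.10 and Cp did not pass the test, at 0.19 ± 0.14.

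Of 19 sarcomere genes 6 fell and 1 rose, also when adjusted over the list alone, and 12 did not pass the test (median -0.14, camera adjusted p = 0.165). Camera called the list lower without normalization between arrays (median -0.02, adjusted p = 0.00423) and under median scaling (median -0.05, adjusted p = 0.00351), where the median of all genes was higher. Tpm1, a tropomyosin, changed by -0.95 ± 0.10, the cardiac troponin I gene Tnni3 by -0.89 ± 0.10 and the Z-disc gene Tcap by -0.86 ± 0.08 (SE), while the intermediate filament gene Des rose by 0.35 ± 0.08. In the hypertrophy and fetal programme 4 genes rose and 3 fell of 15 (camera adjusted p = 0.882). Fhl1, a LIM domain protein, rose by 1.15 ± 0.08 and Rcan1, a calcineurin regulator, by 0.45 ± 0.09. Of 16 genes of calcium handling, ion channels and gap junctions 3 rose and 4 fell (camera adjusted p = 0.882), with Jph2, which tethers the sarcoplasmic reticulum to T-tubules, higher by 1.03 ± 0.14.

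Metabolic lists were not called by camera under quantile normalization. Of 25 oxidative phosphorylation genes 3 fell, Ndufb5 by 0.83 ± 0.14 on the log2 scale, and 22 did not pass the test (camera adjusted p = 0.436). Of these Sdhd and Atp5a1 lost their call without normalization between arrays (adjusted p = 0.197 and 0.0654) and under median scaling (0.164 and 0.0511). Relative to the other genes, camera called this list lower without normalization between arrays (adjusted p = 0.00674) and under median scaling (adjusted p = 0.00511). Fry, which does not compare with other genes, called it and the fatty acid oxidation list lower (adjusted p = 0.000387 and 0.000298). Of 18 fatty acid oxidation genes and PPAR targets 7 fell and 1 rose (camera adjusted p = 0.214), with Angptl4 at -0.94 ± 0.10 (SE) and Acot1 at -0.86 ± 0.14, although a second Acot1 probe gave 0.05. In the glycolysis and glucose uptake list 4 genes rose and 3 fell of 16, or 3 and 2 adjusted over the list alone (camera adjusted p = 0.882). The glucose transporter gene Slc2a1 rose by 1.11 ± 0.08 and Tpi1 changed by -0.48 ± 0.07, with -0.64 and -0.07 at its other probes. Of 9 cholesterol and lipid synthesis genes 3 fell and 1 rose (camera adjusted p = 0.674), with Scd1, a fatty acid desaturase, at -0.96 ± 0.14.

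Stress and survival lists went both ways. Of 27 antioxidant and NRF2 target genes 7 rose and 7 fell (camera adjusted p = 0.882), with the glutathione transferase gene Gsta3 at -1.79 ± 0.09 (SE), while the sulfiredoxin gene Srxn1 rose. The unfolded protein and integrated stress response list had 7 higher and 6 lower of 25 (camera adjusted p = 0.824). Hspa5, an endoplasmic reticulum chaperone, changed by -1.15 ± 0.18 and Nupr1 by 1.01 ± 0.09. Of 13 heat shock genes 3 rose and 5 fell (camera adjusted p = 0.308), with Hspa1a at -0.98 ± 0.12, whose probe may also bind Hspa1b. Of 13 hypoxia response genes 2 rose and 6 fell, or 3 and 6 adjusted over the list alone (camera adjusted p = 0.308), with Ankrd37 at -1.30 ± 0.10. Of 21 apoptosis and survival genes 5 rose and 8 fell (camera adjusted p = 0.436), with Casp1 at -1.44 ± 0.14 and Tnfrsf12a, the TWEAK receptor, at 0.93 ± 0.10. In the FOXO, atrophy and autophagy list 4 rose and 7 fell of 20, or 5 and 7 adjusted over the list alone (camera adjusted p = 0.824), with the autophagy receptor gene Sqstm1 at 0.78 ± 0.09.

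Growth lists were not called by camera, while fry called the 3 lists below lower (adjusted p = 0.00591, 0.000694 and 0.000365 in their order here). Of 17 PI3K, AKT, GSK3 and growth factor signalling genes 3 rose and 3 fell, or 2 and 3 adjusted over the list alone (camera adjusted p = 0.882). Igfbp3 and Igfbp4, which bind insulin-like growth factors, changed by -1.20 ± 0.12 and -1.10 ± 0.09 (SE), and Hbegf by 0.68 ± 0.10. Of 19 cell cycle genes 5 rose and 6 fell, or 5 and 7 adjusted over the list alone (camera adjusted p = 0.542), with the inhibitor gene Cdkn2b at -1.12 ± 0.09 and the cyclin gene Ccnd1 at -1.11 ± 0.10. Of 7 measured genes of the WNT and beta-catenin list 3 fell (camera adjusted p = 0.308), with Dkk3 at -0.79 ± 0.12, a call lost without normalization between arrays. That list holds pathway components and secreted WNT modulators beside targets, so it does not measure target expression alone. For the lists with no separate count given, the counts adjusted over the list alone equalled those over all genes.

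**Figure D3:**
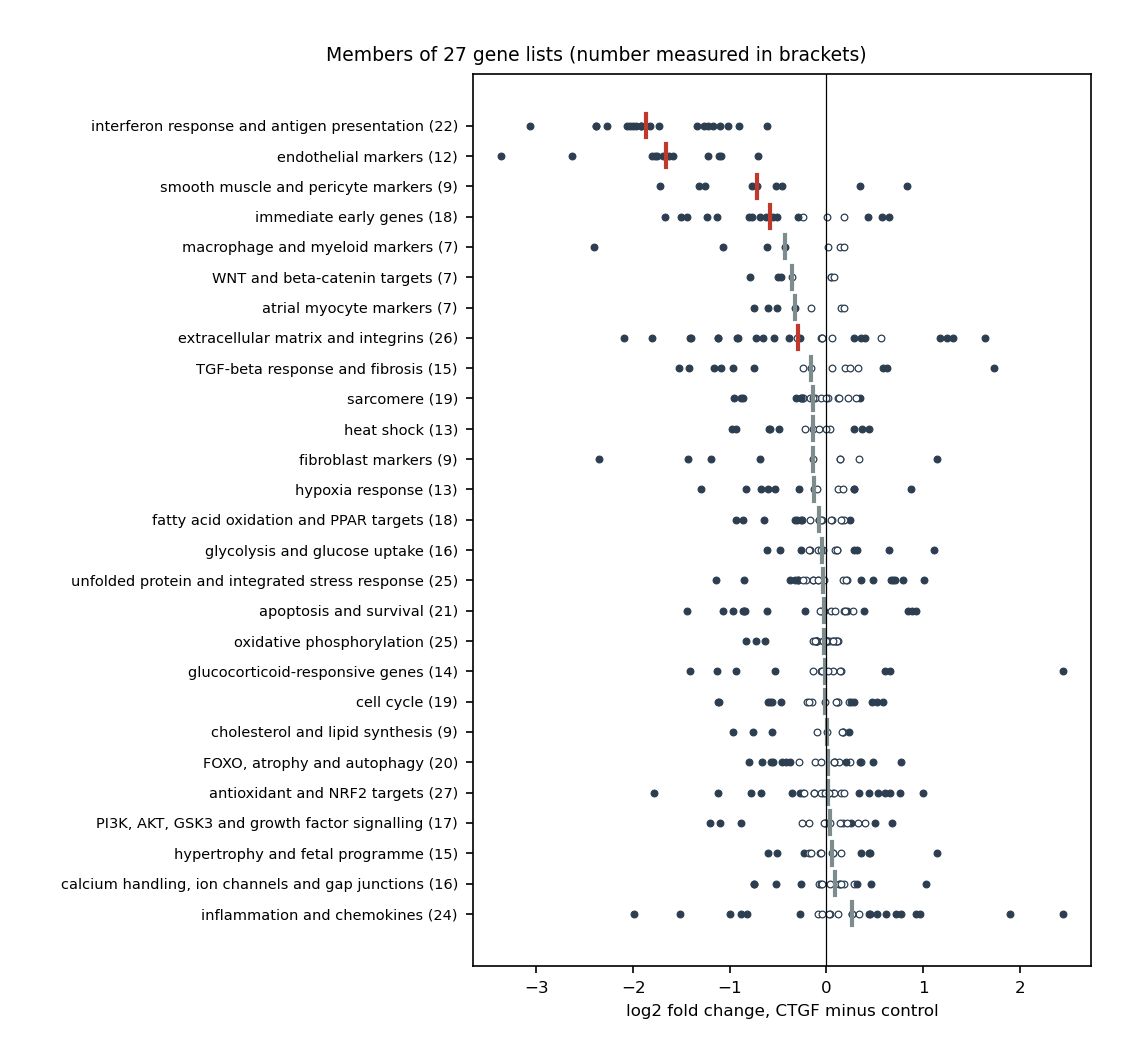
Log2 fold change, CTGF minus control (horizontal axis), of each measured member of the 27 tested gene lists. Filled points are genes called at an adjusted p under 0.05, open points were not called, and bars are list medians, in red for the 5 lists called by camera, all of which fell, from the interferon list at -1.87 to the extracellular matrix list at -0.29. With an estimated correlation only the interferon list stays called, and the other 4 have adjusted p = 0.0753 (endothelial), 0.163 (immediate early), 0.163 (smooth muscle) and 0.428 (extracellular matrix).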

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

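The tests of the shared deviation below were chosen after the deviation had been seen. Among 326 groups of 6 values tested with Dixon's ratio for a single stray array, 20 had such an array, and chance alone gives 5% of groups. Control replicate 1 was the stray array in 8 of them and control replicate 6 in 5.

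Control replicate 1 had a raw 75th percentile of 90.1, the other controls lying between 95.32 and 98.13. Its mean log2 intensity was 10.81 over glycolysis genes, above the others, and 10.85 over heat shock genes, below them. It also had the lowest control value of Atp5a1 (11.82), Hspa1a (7.76), Hspa5 (6.76), Casp1 (5.99) and Cxcl12 (9.34). Control replicate 6 had the lowest control value of the PI3K and growth factor list mean (7.58), Hk1 (5.35), Irs2 (8.99) and Notch3 (5.81), and the highest of Pi16 (6.98). Control replicate 2 stood apart with the highest Birc5 (5.50) and the lowest Apcdd1 (4.75), and control replicate 5 with the lowest Igfbp4 (6.99). Among CTGF arrays, replicate 1 had the highest Tcap (14.59), and replicate 4 the lowest Tpi1 (12.81), P4ha1 (5.74) and Dkk3 (6.10).

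Of 2009 detected probes without a single gene symbol, 871 differed between the groups in the limma fit over all detected probes, 432 higher and 439 lower with CTGF. They belong to no comparison above because their genes are unnamed here.

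CTGF replicate 1 and control replicate 6 deviated from their group means together, with a correlation of 0.505 over probes, where the next highest pair across the groups reached 0.201. Mixing or swapping of these samples would move each toward the other group. On an axis with the control mean at 0 and the CTGF mean at 1, control replicate 6 lay at 0.026, within the 0.0178 to 0.154 of the other controls, and CTGF replicate 1 at 0.923, within the 0.906 to 1.004 of the others. Noise of single probes is argued against by probe pairs of 3012 genes, whose deviations correlated at 0.248 and 0.277 in these arrays and at most at 0.148 in the other 10. A shared technical or biological factor, such as a shared slide or preparation, stays open and was not tested, since the files give neither.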

How the results depend on the processing

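Median scaling and cyclic loess for lists and named genes, and leaving out CTGF replicate 1 with control replicate 6, were added after the data were seen. The slide block was not run, as no slide is given. Leaving out single arrays gave 1955 to 2207 genes higher and 1751 to 1891 lower. Without normalization between arrays 4369 genes were higher and 693 lower, and under median scaling 4193 and 740. Over all detected probes 3576 were higher and 2964 lower. At least 1.5-fold changes numbered 689 and 872, and 2-fold changes 133 and 345. Without both co-deviating arrays 2107 were higher and 1792 lower. With the replicate block 2041 were higher and 1787 lower, and no list lost its call. Same-numbered arrays had residual correlations of -0.074 to 0.048, so no shared effect of the replicate number was seen. Whether samples were paired in another way is not stated in the labels. Only the interferon list kept its call in all 25 alternatives (median -1.94 to -1.34, adjusted p 2.90e-35 to 0.0258). With an estimated correlation, calls were lost for the endothelial (-1.66), immediate early (-0.59), smooth muscle (-0.71) and extracellular matrix (-0.29) lists. The smooth muscle list also lost it over genes detected on all 12 arrays (-0.49), and the extracellular matrix list under cyclic loess (-0.31) and without CTGF replicate 2 or control replicate 2, 3 or 5 (medians over single arrays left out -0.32 to -0.24). Of 126 called named genes 101 kept direction and call in every alternative that measured them and 25 lost the call at least once. Only 106 of the 126 were measured where detection on all 12 arrays was required. Stard10 turned to 0.13 without normalization between arrays and 0.11 under median scaling. Other lists gained a call, 3 without normalization between arrays and the same 3 under median scaling (sarcomere, oxidative phosphorylation, macrophage), 1 with no detection filter (atrial) and 16 with fry. Called named genes had log2 fold changes over 1.5 times smaller in 35 of 126 cases without background correction, 35 on the authors' values, 39 without normalization between arrays and 34 under median scaling. The cause was not tested. Dim signal over background limits small changes.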

Other observations

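The gene families here were formed from symbols after the gene results had been seen, 16 families in all, and the tests of list sizes over other splits, of splits by their balance, of cell shares and of normalization were chosen after the values they bear on. Of 12 histocompatibility 2 genes 10 fell and 2 did not pass the test, with a median log2 fold change of -1.48 (camera adjusted p = 4.99e-07, and adjusted p = 0.00576 with an estimated correlation). H2-Q5 changed by -2.13 ± 0.11 (SE) and H2-T23 by -1.90 ± 0.10, though probes of this family can bind paralogs. H2-K1 and H2-D1 of this family, and Psmb8 and Psmb9 below, are also on the interferon list. The family is therefore not separate from that result. Of 19 semaphorin, plexin and ephrin genes 11 fell and 4 rose (median -0.59, camera adjusted p = 0.0148). The adjusted p was 0.0671 with an estimated correlation. Sema3f changed by -1.70 ± 0.12 and Sema4b by 1.14 ± 0.13. On the same arrays all 12 measured endothelial markers were lower, with a median of -1.66. Of 155 zinc finger protein genes 64 rose and 6 fell (median 0.26, camera adjusted p = 7.09e-05, and adjusted p = 0.00576 with an estimated correlation). These directions were kept without normalization between arrays, under median scaling and under cyclic loess. In the order given, the medians were -1.17, -0.26 and 0.57 without normalization between arrays and -1.19, -0.28 and 0.54 under median scaling. The median of all genes was 0.35 and 0.32 there. The directions were also kept, at smaller sizes, without background correction (-0.82, -0.34 and 0.15 in the order given) and on the authors' normalized values. Of 32 proteasome subunit genes 12 rose and 5 fell (camera adjusted p = 0.233). The immunoproteasome genes Psmb9, Psmb8 and Psmb10 changed by -1.97 ± 0.13, -1.83 ± 0.12 (-0.81 at a second Psmb8 probe) and -0.75 ± 0.08, while Psma5 rose by 0.62 ± 0.09.

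Among 100 splits into 6 and 6 arrays, the real one included, only the real split (1 of 100) called as many as 4080 genes. The highest other split called 395. Every other split mixes the groups, so its spread holds the group difference. The count shows that the arrays differ by group, but not why, and a slide or batch could give the same. For the number of lists called the same count does not exclude chance, since 5 of the 100 splits, the real one included, called at least the real 5 lists, and the highest other called 6. It does not show that chance gives 5 lists either. The 4 other splits kept part of the treatment contrast, with 4 or 5 of the 6 CTGF arrays in 1 group, and the 44 splits with 3 CTGF arrays in each group called 0 lists. The absolute median of the interferon list (1.87, highest other split 1.26) was reached by 1 split, the real one. So was that of the endothelial markers (1.66, highest other 1.15). Both lists were picked after their shifts were seen, and their means on CTGF arrays lay below those on every control array. This outcome was therefore set beforehand and adds no support.

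The endothelial and smooth muscle lists and single markers of fibroblasts fell, and a lower share of such cells in the treated samples is a candidate explanation. With an estimated correlation the lists had adjusted p = 0.0753 and 0.163. A lower share of endothelial cells needs 1 shared fold change, and it cannot be told apart from regulation, since the 7 bright markers spanned 1.78 on the log2 scale only through the largest falls, Ly6c1 and Cldn5, and the other 5 lay between -1.80 and -1.59, a range of 0.212. A lower share of fibroblasts as the whole cause of their markers' falls would lower all abundant markers. Among the 4 markers brightest in controls, Dcn, Lum and Fstl1 had no called change (-0.13 ± 0.15, 0.14 ± 0.10 and 0.14 ± 0.13, SE). Pdgfra, the other, changed by -2.35. The median of the 4 changed by -0.0648 (95% interval -0.174 to 0.0446). The called fall of a fibroblast marker closest to 0 was -0.69, with an upper limit of -0.411. The mean of the same 4 changed by -0.552 (95% interval -0.685 to -0.419), below that limit. Without Pdgfra, left out for its fall, the mean changed by 0.0472 (-0.0908 to 0.185). All these tests were chosen after the values were seen, and a range test that rested on Pdgfra was dropped. Median and mean go opposite ways, and the fall of the mean came from Pdgfra. A lower share as the whole cause would also have lowered Dcn, Lum and Fstl1. Their values argue against it as the whole cause, for these abundant markers. A share that explains a part of the falls stays open.

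The interferon genes may have fallen because fewer endothelial cells carried them. Their median lay 0.21 below that of the endothelial markers (difference -0.211, bootstrap 95% interval -0.703 to 0.415), which does not separate the lists. The bootstrap drew genes within each list as if independent, not arrays, so the interval does not measure the spread between samples. Within groups of 6 arrays the list means correlated with Pearson r = 0.241 (exact permutation p = 0.657, adjusted 0.657) and Spearman rho = 0.486 (exact p = 0.356, adjusted 0.419) with CTGF, and r = 0.528 (exact p = 0.274, adjusted 0.547) and rho = 0.429 (exact p = 0.419, adjusted 0.419) in controls. Without the 2 arrays farthest from the median r was 0.467 and 0.876. The explanation cannot be told apart from a fall within myocytes, as 6 arrays are few and bulk RNA holds all cells. Background correction and normalization as the cause are argued against by a list median of -1.41 at its closest to 0 over 6 other settings.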
